A study of Bos taurus with 12 samples.

How the data were processed

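Messenger RNA levels were measured in biceps brachii muscle of 12 male cattle aged 18 to 20 months, 4 in each of 3 groups. Per the labels, muscle was collected after slaughter and kept in RNAlater, and total RNA was extracted with Trizol, purified on columns, amplified and labelled with Cy3. Each sample was hybridised to 1 array of a 1-colour Agilent bovine design with 21475 probes on 42990 spots other than controls, most probes having 2 spots. The study held 24 animals, 8 per group, and the 12 hybridised samples were those of highest RNA quality, so they were not a random draw. Each array is a separate animal.

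The deposited scanner files hold the intensity of each spot on a linear scale, made by Agilent Feature Extraction version 9.5.1.1 with spatial and multiplicative detrending, per the file headers. The value table that the authors deposited holds intensity on a linear scale as well. Its values rank the spots of each array as the scanner signal does (Spearman correlation of at least 0.999996 on every array), and its maximum of 689500 is shared by all 12 arrays, as quantile normalization gives. Its medians per array ran from 137.25 to 181.167. Its direction and scale follow from this comparison. The steps that made it are not given in the sources used here.

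Log2 of the processed signal was taken, each array's 75th percentile over spots other than controls was subtracted, spots marked as outliers by the scanner software (1 to 7 per array) were left out, and spots of a probe were averaged. The 14703 probes well above background on at least 4 of the 12 arrays were kept, whatever the group. Where a gene had several such probes (929 genes), the probe with the highest mean over all arrays stood for it, which left 13679 genes. Saturated spots (3 to 10 per array) were kept. Levels are given as log2 signal relative to the 75th percentile. Levels of different probes were not set against each other.

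Gene names in the scanner files are those of the array's design. They were updated through a RefSeq gene table of assembly ARS-UCD2.0, used for names only, since the array design names no build. Probe sequences were not mapped anew. Of the 21475 probes, 9923 were matched through a gene number, 3523 through an accession, 395 through a symbol and 2806 through the human match in the probe's description, and 4828 kept the file's name. Where both a table name and a human match existed (9607 probes), 83.2% were the same. The 13679 genes tested included 10706 with a symbol.

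Groups were compared with limma 3.58.1 in R 4.3.3: lmFit on all 12 arrays with 3 group means, so that the groups share 1 estimate of the spread per gene, then eBayes. P-values were adjusted by Benjamini-Hochberg within each of the 3 contrasts, and a gene was called at an adjusted p under 0.05. All p-values are two-sided. Fixed gene lists (32 lists, 657 measured members, 20 of them on over 1 list, 6 to 55 measured per list) were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. They covered glucocorticoid and beta-adrenergic targets, fibre types, energy and lipid metabolism, protein breakdown, stress, immunity, growth, the clock and markers of other cell types in muscle. With a fold stated as at least N-fold, the dim group's mean was taken, per array, from the higher of the probe's own value and the lowest signal among probes well above background.

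The named genes follow a rule set, like the groups, tests, lists and first set of alternatives, before the data were examined. For each contrast they are the 10 largest rises and 10 largest falls among called genes with a symbol and no overlap between the groups' values, up to 3 called members of each list, the 5 genes of smallest unadjusted p in a direction with fewer than 5 calls, and 16 fixed genes, of which MYH2 had no probe under that name. Other genes named below are said to have been chosen after their values were seen.

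The fit and the list test were tested on simulated data: 20 simulations of dexamethasone against control, each with 13679 genes at the measured means and spreads and 200 changed genes. A log2 change of 1 was recovered for 46.1% of changed genes and a log2 change of 2 for 85.6%, with 8.15 false calls on average. A list shifted by a log2 change of 1 was called in all 20 simulations, with 0.05 other lists called on average. Genes vary independently in these simulations, which real genes do not.

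The file headers give the slide and scan day. Slide 1 held control replicates 1 to 3, slide 2 control replicate 4 and dexamethasone replicates 1 to 3, slide 4 dexamethasone plus clenbuterol replicates 1 to 3, and slides 3 and 5 the remaining array of each treated group. The label code of dexamethasone replicate 4 gives another slide than its file header. Slides 2 and 4 were scanned on day 2 and the others on days 1, 3 and 4. The 7 arrays of scan day 2 had a mean negative-control signal of 67.3 to 92.5, and the other 5 of 30.8 to 43.7. Treatment and scan day are therefore largely, though not wholly, confounded, and values with scan day as a term are given for the counts, for the gene lists described most fully and for each list whose call such a term ended or made.

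The alternatives tried were median centring, quantile normalization, normexp background correction with an offset of 50, the authors' table, no filter on dim probes, a filter of all 12 arrays, marked spots kept, the mean over a gene's probes, each probe on its own, an intensity trend, array quality weights, only the groups compared, slide as a fixed or random block, an adjusted p under 0.1, a fold of at least 1.5, and each array left out in turn. Scan day as a fixed block, a block of 2 levels (scan day 2 against the other days) and the slide of the file headers were added after seeing the data. Figures were drawn with matplotlib 3.10.9.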

Results

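Gene expression was measured in the biceps brachii of 12 bulls: 4 untreated controls, 4 given dexamethasone, a synthetic glucocorticoid, and 4 given dexamethasone with clenbuterol, a beta-adrenergic agonist. Dexamethasone alone was fed at 0.75 mg per head for 42 days. The combination was 0.66 mg of dexamethasone per head for 21 days with clenbuterol for 28 days, at 2 mg per head in week 1, 4 mg in week 2 and 6 mg afterwards. The 2 treatments thus differ in the dose and length of dexamethasone as well as in clenbuterol. The time between the last dose and slaughter is not given in the sources used here. Of the spots on each array, 53.2% to 68.7% were well above background, and the number of arrays limits the precision. Arrays of a group correlated at 0.9718 on average over genes, and arrays of different groups at 0.9666. No pair of arrays held identical values, the highest correlation within a group being 0.9838.

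The first comparison asked which muscle genes differ between bulls given dexamethasone and untreated bulls. Most called genes were lower after dexamethasone, among them genes known as targets of the glucocorticoid receptor. FKBP5, a chaperone of that receptor, was 8.45-fold lower (log2 change -3.08 ± 0.58 SE, n = 4 per group, limma adjusted p = 0.0391), at 0.50 ± 0.52 (SD) against 3.58 ± 0.51. RASD1, a small GTPase induced by dexamethasone in other cells, was 4.64-fold lower (log2 change -2.21 ± 0.24, limma adjusted p = 0.00242). NFKBIA, the inhibitor of NF-kappa-B, was 4.03-fold lower and PER1, a clock gene, 4.30-fold lower. In all, limma called 84 of 13679 genes, 80 lower and 4 higher, and 83 of them had no overlap between the groups' 4 values. Over all genes, 6.45% had none, where chance gives 2.86%.

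The glucocorticoid receptor targets fell as a list, with a median log2 change of -0.93 over 27 measured members (camera adjusted p = 2.36e-15; adjusted p = 0.0827 with an estimated correlation; fry adjusted p = 0.00412). Of these members 23 lay below 0, 7 were called lower over all genes tested, and 16 lower when adjusted over the list alone, with none higher in either count. Besides the genes above, CRISPLD2, a secreted protein, was 6.74-fold lower, though its other probe gave a log2 change of -0.095, and PIK3R1, a regulatory subunit of phosphoinositide 3-kinase, was 2.44-fold lower, with log2 changes of -1.14 and -0.76 from its other probes against -1.29. PDK4, the kinase that shuts off pyruvate dehydrogenase, had a log2 change of -1.60 ± 0.35 (limma adjusted p = 0.0759) and GLUL, glutamine synthetase, of -0.93 ± 0.24 (limma adjusted p = 0.117), and neither passed. KLF15 (-1.08) did not pass, nor did TSC22D3 (-0.28), whose probe was dim, at -5.29 in controls. NR3C1, the receptor itself, had a log2 change of -0.23 ± 0.25. The mean of the list per array changed by -1.08 (95% interval -1.501 to -0.664), by -1.46 within scan day 2 (3 treated arrays against 1 control), by -0.78 outside it (1 against 3), and by -1.02 with the 2-level scan block.

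Fibroblast and matrix genes were also lower. Fibroblast markers fell as a list (median -1.06, all 13 measured members below 0, camera adjusted p = 2.75e-08; adjusted p = 0.422 with an estimated correlation), with 0 called over all genes and 8 lower when adjusted over the list alone. Collagens and extracellular matrix fell likewise (median -0.67, 22 of 28 members below 0, camera adjusted p = 5.59e-07; adjusted p = 0.422 with an estimated correlation), with 2 called lower over all genes and 13 over the list alone. The 2 were COL15A1, a basement membrane collagen, at 2.22-fold lower, and MMP2, a collagen-cleaving protease, at 2.6-fold lower. Among the largest falls were MGP, matrix Gla protein (6.48-fold lower, log2 change -2.70 ± 0.43, limma adjusted p = 0.0201), and OSR1, a transcription factor of connective tissue (6.02-fold). CPXM1 and DKK1, a secreted Wnt inhibitor, were also called lower. The sizes of their falls are uncertain, since 1 and 2 of the 4 treated arrays were well above background. Endothelial markers (median 0.185) and smooth muscle markers (median 0.215) did not pass. Within scan day 2 the mean of the fibroblast list changed by -0.75, outside it by -1.62, and with the 2-level block by -1.001. Over all arrays the mean of the collagen list changed by -0.656, with an interval of -1.376 to 0.063, which holds 0. Dexamethasone replicate 1 lay within the range of the controls for fibroblast markers (0.407 against 0.169 to 0.723) and collagens (0.367 against 0.058 to 0.392), so both falls rest on the 3 other treated bulls.

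Leukocyte markers fell as a list (median -0.64, 11 of 15 members below 0, camera adjusted p = 0.00135; adjusted p = 0.599 with an estimated correlation), with 1 called over all genes, CD3E of the T cell receptor (3.34-fold lower), and 2 over the list alone. The mean of the list per array changed by -0.765, with an interval of -1.607 to 0.077, which holds 0. Dexamethasone replicate 1 had the highest leukocyte mean of all 12 arrays (0.871, against 0.291 to 0.604 in controls and -0.980 to -0.285 in the other treated bulls). Without it the median was -1.08, without dexamethasone replicate 2 the list did not pass, and with scan day as a fixed block it did not pass either (camera adjusted p = 0.068). CTSW, a cathepsin of cytotoxic lymphocytes, was called lower, by a size that rests on treated arrays mostly not well above background. LYVE1, a receptor of lymphatic vessels and some macrophages, was 7.14-fold lower. LIPG, endothelial lipase, fell by a log2 change of -3.15 ± 0.32 (limma adjusted p = 0.00242), a size that rests on treated arrays mostly not well above background, and NTRK3, a neurotrophin receptor, was 6.62-fold lower, its other probe giving a log2 change of -1.64 against -2.73. LIPG, CTSW and CPXM1 were well above background on 1 of the 4 treated arrays and on all 4 controls, DKK1 on 2 of 4, and LYVE1, CD3E and NTRK3 on 3 of 4. CCND3, cyclin D3, was 2.15-fold lower, while the cell cycle list did not pass.

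The 4 genes that rose were AMPD3, RGS16, SAMD4A (2.05-fold) and TJAP1 (1.89-fold). AMPD3, an AMP deaminase, was 3.21-fold higher (log2 change 1.69 ± 0.31, limma adjusted p = 0.0377). RGS16, a regulator of G protein signalling, was 4.39-fold higher and well above background on 3 of 4 treated and 1 of 4 control arrays. VGLL2, a muscle transcription cofactor, had the next smallest p and did not pass (log2 change 1.55, limma adjusted p = 0.0621). Heat shock and protein folding genes rose as a list (median 0.54, all 24 members above 0, camera adjusted p = 1.11e-07; adjusted p = 0.422 with an estimated correlation), with 0 called singly by limma in either count. Slow fibre contractile genes rose (median 0.75, 15 of 18 members above 0, camera adjusted p = 0.00121; adjusted p = 0.477 with an estimated correlation; 0 called over all genes and 3 higher over the list alone), within scan day 2 by 1.32 and outside it by 0.06 as means per array, while MYH7, the slow myosin, had a log2 change of 0.23. Over all arrays the slow fibre mean rose by 0.822 (interval 0.098 to 1.546). With the 2-level block it rose by 0.632, with an interval of -0.154 to 1.418, which holds 0. Smaller rises were called for fatty acid oxidation (median 0.41, camera adjusted p = 0.00153; adjusted p = 0.703 with an estimated correlation), oxidative phosphorylation (0.17, 0.00298; 0.809), sterol synthesis (0.26, 0.0118; 0.495) and oxidative stress and metallothioneins (0.28, 0.0297; 0.422), the values in brackets being in the same order. With the 2-level scan block the calls of fatty acid oxidation (camera adjusted p = 0.082), oxidative phosphorylation (0.177) and oxidative stress (0.177) were lost, and with scan day as a fixed block that of oxidative phosphorylation (0.332). The mean of fatty acid oxidation changed by 0.326 within scan day 2 and by 0.004 outside it, and that of oxidative stress by 0.195 and -0.031. Over all arrays the intervals of the means held 0 for fatty acid oxidation, oxidative phosphorylation and oxidative stress. That of sterol synthesis left out 0 (0.07 to 0.667), but with the 2-level scan block it held 0 (-0.025 to 0.663). No member of these 4 lists was called over all genes. Over the list alone, 3 sterol synthesis members were higher and PDK4 of fatty acid oxidation was lower.

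The remaining 22 lists did not pass in this contrast (camera adjusted p from 0.061 for glycolysis and glycogen to 0.933 for blood cell markers). Scan day as a fixed block leaves control replicate 4 as the only control. With it medians were -0.63 for glycolysis and 0.37 for antigen presentation. For immediate early genes the median was -1.03, against 0.34 without the block. Control replicate 4 lay above the other controls for immediate early genes (0.574 against -0.541 to -0.297) and glycolysis (0.368 against -0.044 to 0.213). For antigen presentation it lay within their range. Leaving out 1 array ended the call of oxidative stress in 4 fits, of oxidative phosphorylation in 3, and of sterol synthesis and leukocyte markers in 1 each. The 22 lists include muscle atrophy and ubiquitin ligases, autophagy and lysosome, fast fibre genes, and beta-adrenergic and cAMP targets. Immediate early genes, insulin and IGF signalling, and antigen presentation are among them too. The ubiquitin ligases of muscle atrophy FBXO32 (0.18 ± 0.38) and TRIM63 (-0.82 ± 0.42), the growth inhibitor MSTN (-1.69 ± 0.95), IGF1 (-0.25 ± 0.44), MYH1 (-0.36 ± 0.36), PPARGC1A (-0.09 ± 0.84) and NR4A3 (0.32 ± 1.62) had log2 changes (± SE) that did not pass. Of the treated arrays, MSTN was well above background on 1 of 4 and KLF15 on 2 of 4. The count of 84 fell to 13, all among the 84, with the 2-level scan block. Of the 22 called genes named above, LIPG, RASD1, CRISPLD2 and CCND3 were the 4 that passed with it. FKBP5 had -2.97 ± 0.67 with the block (limma adjusted p = 0.14), a change of similar size with a larger error, and lost its call with scan day (limma adjusted p = 0.309) and in 7 of the fits that left out 1 array. The count fell to 0 with scan day as a fixed block, which compares 3 treated arrays with 1 control. Leaving out dexamethasone replicate 1 raised it to 261 and leaving out control replicate 1 lowered it to 24.

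**Figure D1:**
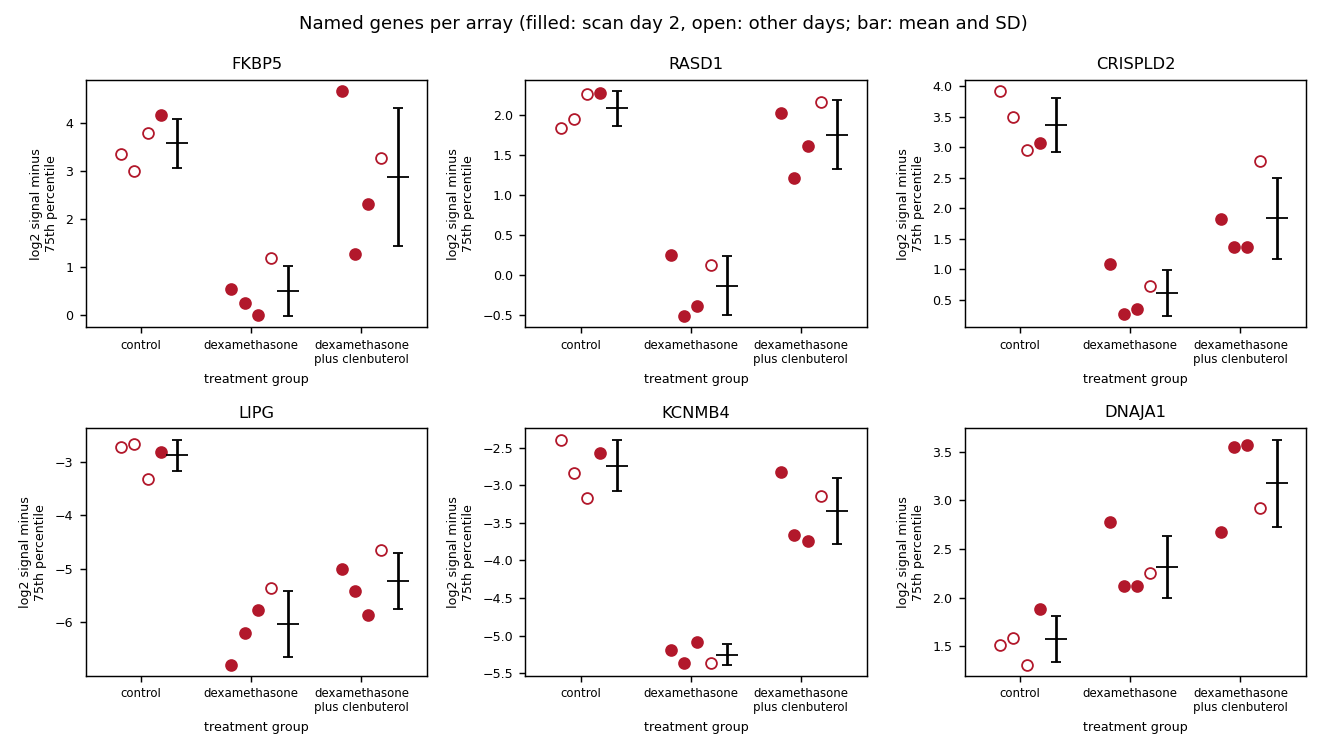
Levels of 6 named genes on each array (y axis, log2 signal minus the array's 75th percentile; x axis, treatment group; 4 points per group, filled for scan day 2 and open for the other days, with the mean and SD as a bar). FKBP5 lay between -0.01 and 1.19 in the 4 dexamethasone bulls and between 2.99 and 4.16 in the 4 controls.

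The second comparison set the combination against untreated bulls. Few genes were called, and a list of chaperone genes was higher by 1 of its 2 camera tests. DNAJA1, a co-chaperone of HSP70, was 3.04-fold higher (log2 change 1.60 ± 0.24, n = 4 per group, limma adjusted p = 0.0482). LIPG was 5.10-fold lower (log2 change -2.35 ± 0.32, limma adjusted p = 0.0354) and EIF4B, a translation initiation factor measured by 1 probe whose sequence was not matched to the gene here, 13.5-fold lower (log2 change -3.76 ± 0.50, limma adjusted p = 0.0354), each well above background on 1 of 4 treated arrays. B3GNT8, a glycosyltransferase, was not well above background on any treated array and was at least 2.41-fold lower. ARHGAP22 was 2.83-fold lower, but its other probe gave a log2 change of -0.23. These 5 and LOC514874 (log2 change 1.14, a gene without a symbol) were the 6 of 13679 genes that limma called, 2 higher and 4 lower. At an unadjusted p under 0.05 there were 1657 genes.

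Heat shock and protein folding rose as a list (median 0.87, 23 of 24 members above 0, camera adjusted p = 8.97e-15; adjusted p = 0.183 with an estimated correlation; fry adjusted p = 0.0136), with 1 called higher over all genes and 18 over the list alone. HSPA1A, the inducible HSP70, had a log2 change of 1.88 ± 0.34 (limma adjusted p = 0.123; its other probes gave 2.72 and 3.63) and STIP1, which joins HSP70 to HSP90, of 1.13 ± 0.19 (limma adjusted p = 0.101), neither of which passed. The mean of the list per array rose by 0.975 (95% interval 0.495 to 1.454), by 0.815 within scan day 2, by 0.95 outside it and by 0.87 with the 2-level block. PLVAP (1.19), an endothelial protein, PHLPP1 (at least 1.82-fold higher) and SLC43A2 (-1.87), an amino acid transporter, were next by p and did not pass.

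Glucocorticoid receptor targets fell as a list here too (median -0.54, 24 of 27 members below 0, camera adjusted p = 1.14e-05; adjusted p = 0.393 with an estimated correlation), with 0 called over all genes and 3 lower over the list alone. FKBP5 had a log2 change of -0.70 ± 0.58 and PDK4 of -1.41 ± 0.35, and neither passed. The mean of this list changed by -0.93 within scan day 2 and by 0.003 outside it, so the fall did not hold in the 1 treated and 3 control arrays of the other days. Leukocyte markers fell (median -0.36, 14 of 15 members below 0, camera adjusted p = 0.0268; adjusted p = 0.794 with an estimated correlation) and so did oxidative phosphorylation (median -0.10, 44 of 55 members below 0, camera adjusted p = 0.00642; adjusted p = 0.912 with an estimated correlation). The intervals of their means per array, -1.353 to 0.33 and -0.46 to 0.233, both hold 0.

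Antigen presentation and interferon response rose (median 0.63, 21 of 22 members above 0, camera adjusted p = 7.29e-05; adjusted p = 0.583 with an estimated correlation), as did polyamine and one-carbon metabolism (median 0.36, 14 of 17, camera adjusted p = 0.00642; adjusted p = 0.183 with an estimated correlation; fry adjusted p = 0.0136), sterol synthesis (median 0.19, 15 of 20, camera adjusted p = 0.00918; adjusted p = 0.58 with an estimated correlation) and endothelial markers (median 0.30, 11 of 13, camera adjusted p = 0.027; adjusted p = 0.794 with an estimated correlation). No member of these lists was called over all genes. The intervals of the means per array held 0 for antigen presentation and endothelial markers. Those of polyamine and one-carbon metabolism and of sterol synthesis left out 0. The mean of antigen presentation changed by 0.461 within scan day 2 and by 1.177 outside it. In that list the combination's replicate 4 stood at 0.94, against -0.16 to 0.299 in the group's other arrays. Over the list alone, 3 polyamine and one-carbon genes and 5 sterol synthesis genes were higher. Antigen presentation, endothelial markers, leukocyte markers and oxidative phosphorylation had 0 calls over the list alone. With the 2-level scan block and with scan day as a fixed block, endothelial markers (camera adjusted p = 0.474 and 0.841) and leukocyte markers (0.0785 and 0.14) did not pass, nor did sterol synthesis with scan day (0.14). The other 24 lists did not pass (camera adjusted p from 0.0612 for fibroblast markers to 0.941 for embryonic and regenerating fibre genes), among them collagens (median 0.12) and beta-adrenergic and cAMP targets (median 0.10). Smooth muscle and pericyte markers did not pass either (camera adjusted p = 0.0968), though the interval of their mean left out 0. The mean rose by 0.323 (interval 0.07 to 0.576), and by 0.366 with the 2-level block (interval 0.075 to 0.657). Scan day as a fixed block leaves control replicate 4 as the only control. With it the median turned to -0.47 for beta-adrenergic targets and from 0.17 to -0.89 for immediate early genes. It was -0.39 for fibroblast markers, -0.35 for glycolysis and 0.65 for slow fibre genes. Control replicate 4 lay above the other controls for immediate early genes, at 0.574 against -0.541 to -0.297. It did so for beta-adrenergic targets (0.434 against -0.295 to 0.156) and glycolysis (0.368 against -0.044 to 0.213) as well. For fibroblast markers and slow fibre genes it lay within their range. Fibroblast markers passed with the 2-level block (median -0.21, camera adjusted p = 0.0433). Leaving out 1 array ended the call of oxidative phosphorylation in 4 fits, of endothelial markers in 3, of leukocyte markers in 2 and of sterol synthesis in 1. The fixed genes GLUL (-0.60), IGF1 (1.14), MSTN (0.36), FBXO32 (-0.26), TRIM63 (-0.06), KLF15 (-0.12), NR3C1 (-0.48), PPARGC1A (-1.69), NR4A3 (-2.32), MYH1 (-0.36) and MYH7 (0.11) had log2 changes that did not pass. TSC22D3 was not well above background on any array of the combination. The count of 6 became 0 with either scan block and 0 without control replicate 1, 2 or 3, without dexamethasone replicate 2 or 4, or without any 1 of the combination's arrays. It became 4 without control replicate 4, 2 without dexamethasone replicate 3 and 11 without dexamethasone replicate 1.

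**Figure D2:**
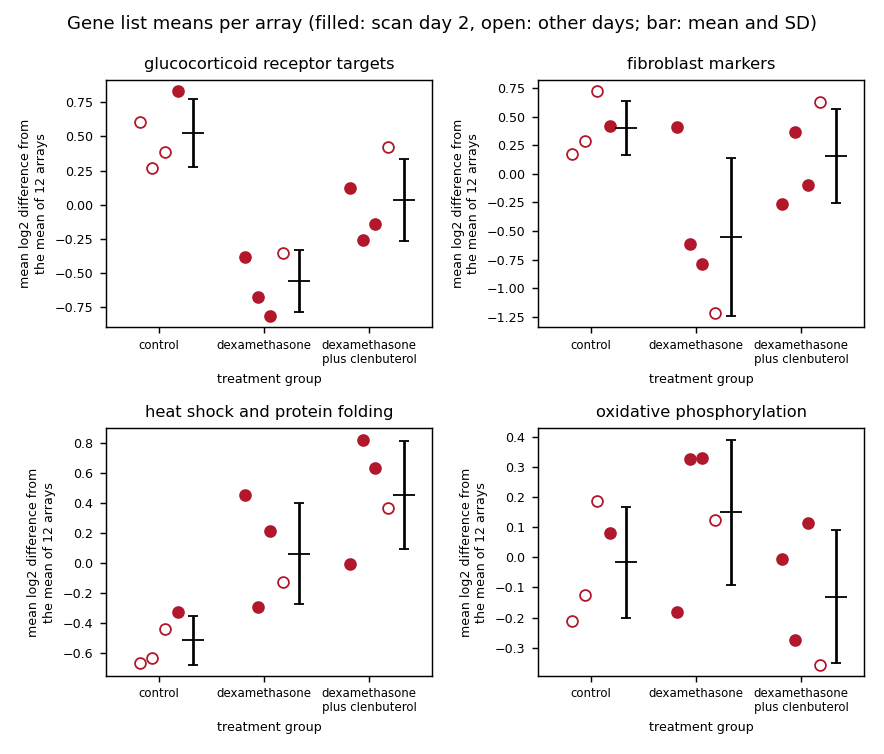
Mean of each of 4 gene lists on each array (y axis, mean over members of the log2 difference from the mean of the 12 arrays; x axis, treatment group; 4 points per group, filled for scan day 2 and open for the other days, with the mean and SD as a bar). Glucocorticoid receptor targets changed by -1.08 from control to dexamethasone, and heat shock genes by 0.975 from control to the combination.

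The third comparison set the combination against dexamethasone alone. KCNMB4, a subunit of calcium-activated potassium channels, was 3.75-fold higher with the combination (log2 change 1.91 ± 0.23, n = 4 per group, limma adjusted p = 0.0319) and RASD1 3.70-fold higher (log2 change 1.89 ± 0.24, limma adjusted p = 0.0319). KCNMB4 was well above background on 1 of 4 dexamethasone arrays. These were the 2 genes of 13679 that limma called, and both were among those lower after dexamethasone alone (KCNMB4 by a log2 change of -2.51). Both comparisons use the same dexamethasone arrays, which by itself favours that overlap. At an unadjusted p under 0.05 there were 1506. The next by p, none passing, were KRT25 (at least 1.77-fold higher), INSL3 (1.39) and KERA, keratocan (3.49, with 1 of 4 dexamethasone arrays well above background), and in the other direction SLC4A4, a bicarbonate cotransporter (-1.75), BACH2 (-1.48), TCEAL1 (-0.92), NOCT, nocturnin (-1.14), and SYTL3 (-1.98).

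Glucocorticoid receptor targets rose as a list (median 0.58, 21 of 27 members above 0, camera adjusted p = 2.18e-05; adjusted p = 0.418 with an estimated correlation), with 1 called over all genes and 9 higher over the list alone. FKBP5 had a log2 change of 2.38 ± 0.58 (limma adjusted p = 0.175), with no overlap between the groups. The mean of the list changed by 0.53 within scan day 2, where each group had 3 arrays, and by 0.78 outside it. By the file headers no slide held arrays of both groups, so slide and treatment cannot be told apart in this contrast. Collagens and extracellular matrix (median 0.73, 27 of 28 members above 0, camera adjusted p = 1.34e-07; adjusted p = 0.418 with an estimated correlation) and fibroblast markers (median 0.725, 13 of 13, camera adjusted p = 0.000127; adjusted p = 0.637 with an estimated correlation) rose, with 0 called over all genes and 3 and 0 over the list alone. Their means changed by 0.37 and 0.33 within scan day 2 and by 1.58 and 1.85 outside it. Over all arrays they changed by 0.673 (interval -0.047 to 1.393) and 0.711 (interval -0.062 to 1.484), and both intervals hold 0. Dexamethasone replicate 1 lay within the range of the combination for both lists, so these rises rest on the 3 other dexamethasone bulls. With scan day as a fixed block the fibroblast list did not pass (camera adjusted p = 0.2).

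Oxidative phosphorylation fell, with all 55 members below 0 (median -0.28, camera adjusted p = 1.21e-10; adjusted p = 0.637 with an estimated correlation) and 0 called singly by limma in either count. Its mean per array changed by -0.28, with an interval of -0.627 to 0.067, which holds 0. Dexamethasone replicate 1 (-0.183) lay within the combination's range (-0.356 to 0.113). Fatty acid oxidation (median -0.23, camera adjusted p = 0.00382; adjusted p = 0.672 with an estimated correlation), oxidative stress and metallothioneins (-0.12, 0.0135; 0.418) and beta-adrenergic and cAMP targets (-0.39, 0.0374; 0.637) fell too, the values in brackets being in the same order. Of the beta-adrenergic list 15 of 20 members lay below 0, among them NR4A3 (-2.64 ± 1.62) and PPARGC1A (-1.59 ± 0.84), neither of which passed. Heat shock (median 0.35, camera adjusted p = 0.00304; adjusted p = 0.637 with an estimated correlation), antigen presentation (0.38, 0.00322; 0.637), insulin and IGF signalling (0.22, 0.0258; 0.418) and cell cycle genes (0.24, 0.0496; 0.637) rose as lists. The intervals of the means per array held 0 for fatty acid oxidation, beta-adrenergic targets, heat shock, antigen presentation and the cell cycle. Those of oxidative stress and of insulin and IGF signalling left out 0. With scan day as a fixed block, antigen presentation (camera adjusted p = 0.929), insulin and IGF signalling (0.215), cell cycle genes (0.276) and the beta-adrenergic list (0.127) did not pass. The mean of antigen presentation changed by -0.036 within scan day 2 and by 1.543 outside it, and the cell cycle call was lost in 18 of 30 alternatives, among them the 2-level block (0.0561). Over the list alone the counts were 1 lower for oxidative stress, 1 lower for the beta-adrenergic list, 2 higher for heat shock, 1 higher for antigen presentation and 2 higher for the cell cycle, and 0 for the other 2 lists.

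The other 21 lists did not pass (camera adjusted p from 0.0989 for cytosolic ribosomal proteins to 0.97 for adipocyte markers). With scan day as a fixed block ribosomal proteins did (median -0.11, camera adjusted p = 0.021). Polyamine and one-carbon metabolism did not pass (camera adjusted p = 0.155), though the interval of its mean left out 0. The mean rose by 0.251 (interval 0.058 to 0.444), and with the 2-level block the interval was 0.078 to 0.424. Leaving out 1 array ended the cell cycle call in 8 fits and the beta-adrenergic call in 3, and those of fatty acid oxidation, insulin and IGF signalling, antigen presentation and heat shock in 2 each and of oxidative stress in 1. Log2 changes of these further fixed genes did not pass: IGF1 (1.39), MSTN (2.05), TRIM63 (0.76), KLF15 (0.96), GLUL (0.33), FBXO32 (-0.44), NR3C1 (-0.26), MYH7 (-0.12), PDK4 (0.19) and MYH1 (0.00). The count of 2 became 0 with either scan block, 74 (63 higher) without dexamethasone replicate 1, 15 without the combination's replicate 2, 3 without control replicate 3, 1 without the combination's replicate 3 and 0 without control replicate 1, 2 or 4, dexamethasone replicate 2, 3 or 4, or the combination's replicate 4.

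Both treatments were compared with the same 4 controls. LIPG, B3GNT8 and EIF4B were called lower in both, and no gene was called higher in both. With either scan block or no filter on dim probes 0 genes were called in both, and leaving out 1 array gave 0 to 4. Simulated unchanged groups gave 0 shared calls on average over 100 simulations. In the 20 simulations of the fit, a contrast without change had 0.05 calls on average. With so few calls, hardly any could be shared. Independent lists of these sizes would share 0.0234 lower genes, but lists that rest on the same controls are not independent. Neither value can therefore decide whether the 3 shared genes exceed what shared controls give. With the controls split 2 and 2, in 6 ways, dexamethasone had 1 to 23 calls and the combination 0 to 1, too few to test shared calls. The fold changes of the 2 treatments correlated at 0.58 across genes, which are not independent replicates, where unchanged groups give 0.501. Their covariance was 0.126 against a simulated 0.0595, a difference of 0.0667, and with split controls the covariance ran from 0.061 to 0.0888. These reference values leave out scan day, which 3 of 4 arrays of each treated group shared against 1 of 4 controls, so part of the excess may come from it. Of the 80 genes that fell after dexamethasone alone, 78 were higher in the combination than in dexamethasone alone. Their median log2 change from control was -1.59 after dexamethasone and -0.59 after the combination. These genes were chosen for being low in the dexamethasone arrays, which by itself favours that direction.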

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

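The tests of scan day, the count of splits alike in scan day, and the test of cell types named for fibroblasts below were chosen after the results were seen. The tests with the fibroblast covariate, with array brightness and over other splits of the arrays were set before their results were seen.

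In 17 of 270 groups of 4 arrays (6.3%), 1 array lay far from the other 3 by Dixon's gap test. Chance flags about 1 in 20 groups. Control replicate 4 had a negative-control signal of 92.5 against 35.8 to 43.7, being the 1 control scanned on day 2, and its HSPA1A level was 7.15 against 6.07 to 6.17. Dexamethasone replicate 1 stood apart in 4 of the 17: embryonic and regenerating fibre genes at 1.41 (others -0.61 to -0.40), nerve and Schwann cell markers at -0.38 (others 0.30 to 0.40), VGLL2 at 0.81 (others 1.96 to 2.20) and INSL3 at -4.20 (others -4.91 to -4.82). In dexamethasone replicate 4 the circadian clock list stood at 0.40 (others -0.12 to -0.07) and ARHGAP22 at -1.32 (others -1.66 to -1.61).

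The combination's replicate 3 had the lowest CCND3 (0.74), CTSW (-5.21) and autophagy list mean (-0.13) of its group. Its replicate 2 had MSTN at -6.88 against -2.82 to -2.04, its replicate 1 a sterol synthesis mean of -0.13 against 0.26 to 0.30, and its replicate 4 SYTL3 at -3.09 against -4.46 to -4.25. NFKBIA was 1.17 in dexamethasone replicate 3 against 1.57 to 1.61, COL15A1 was 0.12 in dexamethasone replicate 2 against 0.61 to 0.63, and TJAP1 was 1.19 in control replicate 3 against 1.33 to 1.35.

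Glucocorticoid receptor targets were lower in dexamethasone than in control. With the 2-level scan block the change of the list's mean was -1.02 (95% interval -1.505 to -0.534), against -1.08 without it. This argues against a shift between scan day 2 and the other days as the whole cause. The block takes the other days as alike. With the fibroblast list's mean in the fit the change was -0.99 (95% interval -1.60 to -0.38). This argues against a lower share of fibroblasts, as measured by that mean, as the whole cause. The mean is an imprecise measure of the share, so the fit may remove only part of its effect and cannot exclude it. The treatment itself, for instance through suppression of the animals' own cortisol after long exposure, may account for the fall, but no hormone value was analysed here and this was not tested. Time since the last dose stays open as well.

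Heat shock genes were higher in the combination than in control. With the 2-level scan block the change was 0.87 (95% interval 0.33 to 1.41), and with each array's 75th percentile in the fit it was 0.89 (95% interval 0.37 to 1.42), against 0.975 without a term. These values argue against array brightness, and against a shift between scan day 2 and the other days, as the whole cause. The block takes the other days as alike. By the file headers no slide held both control and combination arrays, so a slide effect cannot be told apart from treatment. Clenbuterol, dexamethasone and handling of the animals or tissue could each raise these genes, and the design does not part them.

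Fibroblast markers were lower in dexamethasone than in control. With the 2-level scan block the change was -1.001 (95% interval -1.92 to -0.08), against -0.954 without it. The interval leaves out 0, which argues against a shift between scan day 2 and the other days as the whole cause. Its upper limit lies nearer 0 than -0.238, the bound held to in this test. Such a shift as most of the cause therefore stays open, as does a difference among the other days. Dexamethasone replicate 1 lay at 0.407, within the controls (0.169 to 0.723), so the fall rests on the 3 other treated bulls. A lower share of every cell type other than muscle fibres would lower endothelial markers alike, but the fibroblast minus endothelial change was -1.12 (95% interval -1.95 to -0.29). A lower share of fibroblasts and lower expression within them both stay open.

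For dexamethasone against control, 1 of the 35 splits of the 8 arrays, the real one, called as many genes: 84, against at most 13 in the others, so chance can be excluded at 0.05 if all splits are taken as alike. They are not alike in scan day: 16 of them share the real balance of scan day 2 arrays, too few for a share under 0.05, and the highest other of these also called 13. For the combination against control, 3 of the 35 splits called at least the real 6 genes, the highest other calling 11. For the combination against dexamethasone, 5 of 35 called at least the real 2, the highest other calling 14. Chance cannot be excluded for these 2 counts.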

How the results depend on the processing

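The scan day blocks and the slide of the file headers were chosen after seeing the data. For dexamethasone against control, the count of 84 became 13 with the 2-level scan block, 0 with scan day or slide (label code or file header) as a fixed block or within 1 slide, 25 with no filter on dim probes, 212 at an adjusted p under 0.1 and 287 with array quality weights. Leaving out 1 array gave 24 to 261. For the combination against control, the count of 6 became 0 with the 2-level block, scan day, label slide as a fixed block, header slide as a random block, no filter or a filter of all 12 arrays. It was 2 with the mean over probes, 3 with quantile normalization or only the groups compared, 128 with array weights, and 0 to 11 leaving out 1 array. Of the 6 calls 2 were higher, against 0 of 5 with median centring, 0 of 3 with quantile normalization and 72 of 128 with array weights. For the combination against dexamethasone, the count of 2 became 0 with median centring, quantile normalization, the mean over probes, no filter, only the groups compared, either scan block, or label slide as a fixed block or within 1 slide, or header slide as a random block. It was 1 with normexp or a filter of all arrays, and 0 to 74 leaving out 1 array. The 3 genes called in both became 38 with array weights, 1 with quantile normalization or only the groups compared, 0 with either scan block, label slide fixed, header slide random, no filter or the stricter filter, and 0 to 4 leaving out 1 array. Fixed blocks keep 1 control in each comparison with control, and label slide as a fixed block keeps 1 dexamethasone array in the third contrast. Fewer arrays therefore inform them. Otherwise the cause was not tested. Header slide as a fixed block could not be fitted for the combination.

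With an estimated correlation 0, 0 and 0 lists were called in the 3 contrasts, in place of 10, 8 and 11, and with fry 1, 2 and 0. Scan day as a fixed block gave 7 in the third. Immediate early genes, not called, turned to -1.03 (dexamethasone against control, scan day or either slide as a fixed block). For the combination they turned to -1.43 (label slide) and -0.89 (scan day). These fits keep control replicate 4 as the only control, which stood at 0.574 against -0.541 to -0.297 in the other controls. In the third contrast label slide as a fixed block gave glycolysis -0.53, fatty acid synthesis 0.45, fatty acid oxidation 0.10 and oxidative stress 0.07. These values set combination arrays against dexamethasone replicate 4 alone, whose label code and file header give different slides. Scan day turned the test of antigen presentation (median 0.084). Its cause was not tested. Over 29 called values of named genes and 846 alternatives, 395 no longer passed and 0 changed sign past the threshold. Arrays of scan day 2 had fewer spots above background, which limits dim genes such as LIPG. No paired analysis was possible because the labels give no pairing of animals across groups.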

Other observations

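The genes named in this part outside the fixed list of genes, and the relation between genes, were chosen after their values were seen. ARG2, a mitochondrial arginase, had log2 changes of 2.89 ± 0.68 (SE) after dexamethasone (limma adjusted p = 0.085) and 3.23 ± 0.68 after the combination (limma adjusted p = 0.149), and PHGDH and PSPH, enzymes of serine synthesis, had 1.05 and 1.17 after the combination and 0.16 and 0.20 after dexamethasone. None of these passed over all genes. CD163, a scavenger receptor of macrophages that glucocorticoids are known to induce, had log2 changes of -2.73 ± 0.62 after dexamethasone (limma adjusted p = 0.0778) and -2.01 ± 0.62 after the combination. CREM, a cAMP-responsive transcription factor, had -0.02 after dexamethasone and -1.24 ± 0.28 after the combination (limma adjusted p = 0.165).

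NR4A3 and PPARGC1A, both known to respond to exercise and beta-adrenergic signals, varied widely within each group. NR4A3 ran from -0.56 to 3.70 in controls, from -1.85 to 3.68 after dexamethasone and from -3.53 to 3.74 after the combination. After each group's mean was subtracted, the 2 genes moved together over the 12 bulls (Pearson r = 0.959, permutation p = 0.00034, adjusted p = 0.0357; Spearman rho = 0.923, permutation p = 0.00059, adjusted p = 0.0619). This was the strongest of 105 pairs of fixed genes, with 100000 permutations within groups, and the 1 pair that passed by r. Without the 2 arrays farthest from the median of PPARGC1A, r was 0.929, and within the 7 arrays of scan day 2 it was 0.928. The 5 other arrays were too few for a value of their own.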
